A study of Mus musculus with 12 samples.

How the data were processed

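RNA sequencing was deposited for 12 libraries of mouse mTECs, a renal tubular epithelial cell line: control (NC) and FH-silenced (KD) cells, basal and after TGF-β1, with 3 libraries per group. Per the labels, total RNA was extracted with TRIzol and mRNA libraries were made with a BGI kit; the labels do not state the silencing reagent or the length or dose of the TGF-β1 treatment. The submitters' processing notes name HISAT2, Bowtie2, RSEM 1.3.1 and DESeq2 1.34.0 without saying which step each served, and the build hg38, a human one, although the samples are from mouse. No coordinates are given here for that reason, and gene names are those of the deposited Entrez IDs in the RefSeq table of GRCm38.p6.

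The authors deposited 2 tables of RefSeq transcripts with Entrez gene IDs, 1 for the basal and 1 for the TGF-β1 libraries, each with several value columns per library. The read count columns hold estimated counts (expected counts, not whole numbers) per transcript, per the file headers and the values, and the TPM columns hold TPM per the file headers, scaled to the same sum in every library. FPKM and normalized read count columns were not used here. The basal table lists 54463 transcripts of 15990 genes, none of them at 0 in all of its libraries, and that of TGF-β1 lists 60686 transcripts of 17659 genes, of which 5433 transcripts are at 0 throughout. Estimated counts and TPM were summed per Entrez ID, estimated counts were rounded, and the 15802 genes listed in both tables were used. The genes listed in 1 table only hold at most 0.012% of a library's counts. Library totals were 17651213 to 18462872 estimated counts. Members of the list of mitochondrially encoded genes are not in the tables, and those genes were not analysed here.

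Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling (factors 0.978 to 1.025), filterByExpr with its defaults, 1 coefficient per group over all 12 libraries, quasi-likelihood F-tests with 8 residual degrees of freedom, and calls at a Benjamini-Hochberg adjusted p under 0.05 over the 11707 genes left. The 5 contrasts were KD against NC in basal and in TGF-β1 libraries, TGF-β1 against basal libraries in NC and in KD cells, and the interaction. Errors of log2 changes are standard errors of the fit, and CPM are the counts scaled by TMM and library size. The biological coefficient of variation was 4.6%. Replicates of a group differed by more than sampling noise: the chi-square per gene between pairs was 1.68 to 13.68, the highest between NC replicates 1 and 3. The fit was tested on simulated data with 200 changed genes. At 1.25-fold it recovered 63% of them for silencing in basal cells, 67.5% for silencing with TGF-β1 and 35% for the interaction. At 1.5-fold it recovered 88%, 82% and 76%, with 2 to 11 false calls over all settings. Each gene was drawn independently there. The false calls from differences that many genes of a library share are therefore not measured.

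Gene lists (29, of which 23 had 5 or more tested members) were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted within each contrast over the lists tested, and Fh1 was left out of every list. On simulated data, with each gene drawn independently, camera called 10 of 10 lists shifted by 1.15-fold and 0 of 10 unshifted ones. That simulation cannot show how many false calls arise where genes of a list move together. The estimated correlation between genes reached 0.195, for glycolysis. With an estimated correlation between genes, 5 of 8 list calls in basal silencing, 3 of 6 with TGF-β1, 2 of 10 for TGF-β1 in control cells, 6 of 9 in silenced cells and 5 of 9 in the interaction held. For genes of each list, p-values were also adjusted over the list alone.

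The groups, contrasts, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes, per contrast, Fh1 and Akap12, the 6 called genes with the largest log2 increases and the 6 with the largest decreases among genes with a mean of at least 5 CPM in a group compared, no overlap between the groups and no predicted or clone name, up to 4 called members of each list described (or the 1 with the smallest p where none was called), and the markers Col1a1, Fn1, Acta2, Vim, Cdh1, Ccn2, Smad7, Il6, Ccl2, Hmox1 and Nqo1. Il6 and Nqo1 are not among the genes tested, and some genes that the rule takes are not reported here. For the interaction, no overlap between NC and KD or between NC+TGF-β1 and KD+TGF-β1 libraries was taken as enough, a choice made after the data were seen.

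The alternatives were size factors of DESeq2 in edgeR, no low-count filter, DESeq2 1.42.0 itself, replicate number as a block, only the 2 groups compared in the fit, an absolute log2 change of at least 1, limma on log2 (TPM + 1), an estimated correlation and fry for the lists, the genes above the median level for the correlations, and leaving out each of the 12 libraries in turn. Chosen after seeing the data was the union of the genes of both tables, with 0 for a gene not listed. So was leaving out genes whose 3' UTR holds an enriched word and genes with no annotated 3' UTR. There the list tests were run again, while the gene calls are those of the main fit among the 7987 genes left.

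Words of 7 bases (16384) were sought in the longest annotated 3' UTR per gene (GENCODE M21, at least 50 bases, 95.7% of the tested genes). For each word, the genes of a set that hold it were counted. That number was compared with the one expected from all genes searched, the set included, in 10 strata of UTR length. A Poisson tail was used, with a Bonferroni correction at 0.01. In a self-test a planted word ranked first in 20 of 20 sets and no word passed in 20 random sets. A normal approximation was used first and passed a word in 4 of the 20 random sets; it was replaced after the results had been seen. Under it the genes higher in both silencing contrasts had 1 word past 0.01, GGTGCTA (0.00651), at 0.841 by the Poisson tail. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.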

Results

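Fumarate hydratase (gene Fh1) turns fumarate into malate in the tricarboxylic acid cycle, and the series asks how it bears on fibrosis of the kidney. Mouse renal tubular epithelial cells (mTECs) were sequenced as controls (NC) or with Fh1 silenced (KD), without or with TGF-β1, a cytokine that drives fibrotic change in tubular cells, with 3 libraries in each of 4 groups. Across the 11707 genes tested, the first principal component (78% of the variance) parted the TGF-β1 libraries from the basal ones. NC replicate 1 stood apart on the second component (3.9%), beyond the range of -8.1 to 7.2 of the other 11 libraries. The basal and the TGF-β1 libraries come in separate deposited tables that list different transcripts. In every comparison across them the cytokine and the table or experiment cannot be told apart. The labels do not say whether the replicates of a group are separate cultures, and the p-values measure the spread between these samples, which can be technical.

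Silencing lowered the Fh1 transcript in both settings, and further in the TGF-β1 libraries. Fh1 (Entrez 14194) stood at 52.9 ± 1.37 CPM (mean ± SD of 3 libraries) in NC and 29.85 ± 1.38 in KD cells. This is a log2 change of -0.83 (SE 0.045, adjusted p = 6.47e-07) that left 56.4% of the control level (54.7 to 58.2% at ± 1 SE). With TGF-β1 it stood at 49.6 ± 0.175 in NC and 14.2 ± 0.726 in KD cells. That is a log2 change of -1.81 (SE 0.051, adjusted p = 8.95e-11) that left 28.6% (27.6 to 29.6%). The difference between these changes was -0.98 on the log2 scale (SE 0.069, adjusted p = 8.18e-06). TGF-β1 itself went with a log2 change in Fh1 of -0.09 in control cells (adjusted p = 0.072) and of -1.07 in silenced cells (adjusted p = 4.22e-10). The control-cell value passed the threshold without NC replicate 1, at -0.115 (adjusted p = 0.0496). Akap12 (Entrez 83397) codes for a scaffold of protein kinase A and is named in the series title. It rose with silencing from 546.6 ± 15 to 660 ± 13.2 CPM in basal cells (log2 change 0.27, SE 0.029, adjusted p = 0.00013). With TGF-β1 it rose with silencing from 751 ± 9.22 to 877.6 ± 23.4 CPM (0.225, SE 0.029, adjusted p = 0.000314). Akap12 also rose with TGF-β1 itself, by 0.46 in control cells (adjusted p = 7.23e-09) and 0.41 in silenced cells (adjusted p = 2.15e-08). Its interaction was -0.05 (adjusted p = 0.728). In each of these 4 comparisons of Akap12, and in the 2 of silencing for Fh1, the 3 libraries of one group did not overlap with the 3 of the other.

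**Figure D1:**
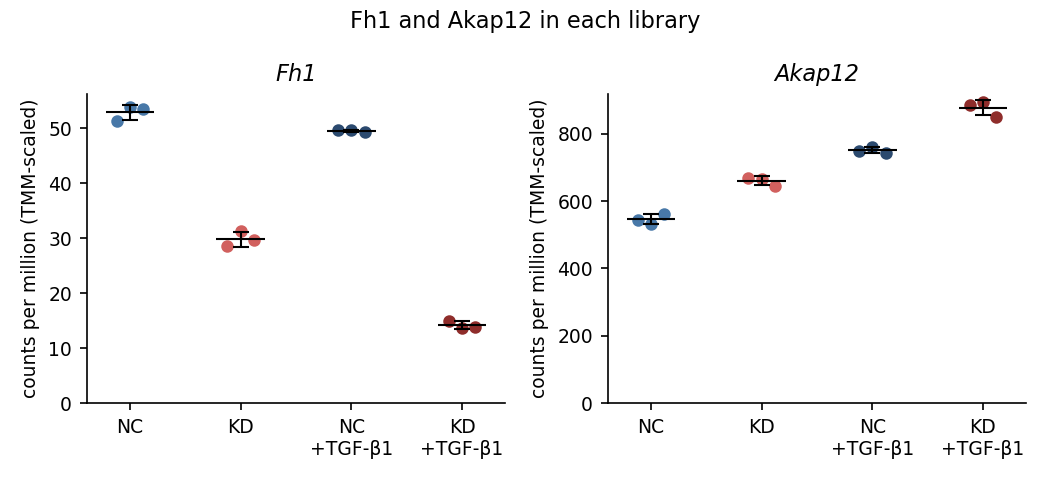
Fh1 and Akap12 in CPM (counts scaled to library size; vertical axis) in the 4 groups, with bars for the group mean, error bars for ± 1 SD and points for the 3 libraries. Fh1 fell to 56.4% of the control level in basal cells and to 28.6% with TGF-β1, while Akap12 rose in both.

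In basal cells, silencing of Fh1 went with higher inflammatory and immediate early transcripts and with lower transcripts of the ATF4 program. The changes were small: among the 429 called genes (169 higher, 260 lower) the median change was 1.17-fold, and 6 genes passed 2-fold. Egr1 (Entrez 13653), an immediate early transcription factor, rose from 24.4 ± 1.98 to 43.4 ± 1.18 CPM (log2 change 0.83, SE 0.06, adjusted p = 4.61e-06). Mbd6 (110962; 0.60), a methyl-CpG-binding domain protein, and F3 (14066; 0.59), the tissue factor that starts coagulation, rose as well. So did Txnip (56338; 0.57), the thioredoxin-interacting protein, and Tanc2 (77097; 0.56), a scaffold protein. The adjusted p of these 4 genes were 4.61e-06 to 0.00675. H1f2 (50708), a linker histone whose reads are hard to tell from those of its paralogs, rose by 0.70 (adjusted p = 0.00236). Besides Fh1, the largest decreases by the fixed rule were those of C1qtnf1 (56745; -0.63, adjusted p = 0.0186), a secreted C1q-like protein, and Sh3yl1 (24057; -0.57, adjusted p = 0.000646), a phosphoinositide-binding adaptor. Then came the kinesin Kif12 (16552; -0.52, adjusted p = 0.0435), the protein kinase Prkch (18755; -0.52, adjusted p = 0.0476) and the protein kinase Dmpk (13400; -0.48, adjusted p = 0.00303). Of the 11707 genes tested, 22.7% had no overlap between the 3 libraries of each group, against 10% by chance. All 429 called genes are among them, as a call on the same libraries favors.

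Of 32 tested genes of inflammation and NF-κB, 8 rose and 1 fell (14 and 4 adjusted over the list alone; list test adjusted p = 6.9e-05). Among those that rose were Traf1 (log2 change 0.56), a TNF receptor adaptor, the neutrophil chemokines Cxcl1 (0.51) and Cxcl2 (0.50), and Tnfaip3 (0.39), a brake on NF-κB. Of 19 immediate early genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.000145). Fos had 10, 14 and 19 estimated counts in NC and 37, 40 and 32 in KD libraries. The phosphatase Dusp5 rose by 0.26 and the transcription factor Klf6 by 0.24. Of 22 interferon genes, 2 rose (also 2 adjusted over the list alone; adjusted p = 0.00859). These were Ifit1, from 3, 3 and 3 counts to 16, 12 and 14, and the chemokine Cxcl10, from 15, 11 and 12 to 49, 50 and 39. Of 33 genes of the ATF4 and integrated stress response, 10 fell and 0 rose (11 and 1 adjusted over the list alone; adjusted p = 1.09e-06). The transcription factor Atf5 was at -0.31, the glutathione-degrading Chac1 at -0.30, the stress regulator Nupr1 at -0.265 and the mitochondrial serine hydroxymethyltransferase Shmt2 at -0.25. Of 19 mesenchymal and contractile genes, 2 rose (3 adjusted over the list alone; adjusted p = 0.00256). They were the actin crosslinker Actn1 (0.22) and the calponin Cnn2 (0.17). Of 31 genes of the extracellular matrix, 6 rose and 2 fell (7 and 2 adjusted over the list alone). The basement membrane collagens Col4a2 and Col4a1 rose by 0.305 and 0.30, and Col12a1 was at -0.30 and the laminin Lamc1 at -0.27. That list tested as higher (adjusted p = 0.00973; adjusted p = 0.133 with an estimated correlation), with a median of 0.05 and a mean of -0.02. Of 31 TGF-β pathway genes and targets, 5 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.0109, and adjusted p = 0.133 with an estimated correlation). Ccn1, a matricellular protein, was at 0.215, the adaptor Nedd9 at -0.34 and Id1 at -0.30. Of 40 cell cycle genes, 2 fell and 0 rose (3 and 0 adjusted over the list alone; adjusted p = 0.00859, and adjusted p = 0.0923 with an estimated correlation). They were Rrm1 (-0.31), a subunit of ribonucleotide reductase, and Tpx2 (-0.155), a spindle protein. Among the markers named in advance, Ccn2, a growth factor of fibrosis, rose by 0.20 (adjusted p = 0.00462). The values of Fn1 (fibronectin; 0.09, adjusted p = 0.0832), Cdh1 (E-cadherin; 0.085, adjusted p = 0.0769), Ccl2 (0.60, adjusted p = 0.0801), Smad7 (0.11, adjusted p = 0.22) and Hmox1 (0.05, adjusted p = 0.761) did not pass. Col1a1 had 8, 17 and 13 counts in NC and 12, 10 and 18 in KD libraries. Vim had 2, 6 and 6 against 3, 1 and 4, and Acta2 had at most 2 in a library.

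**Figure D2:**
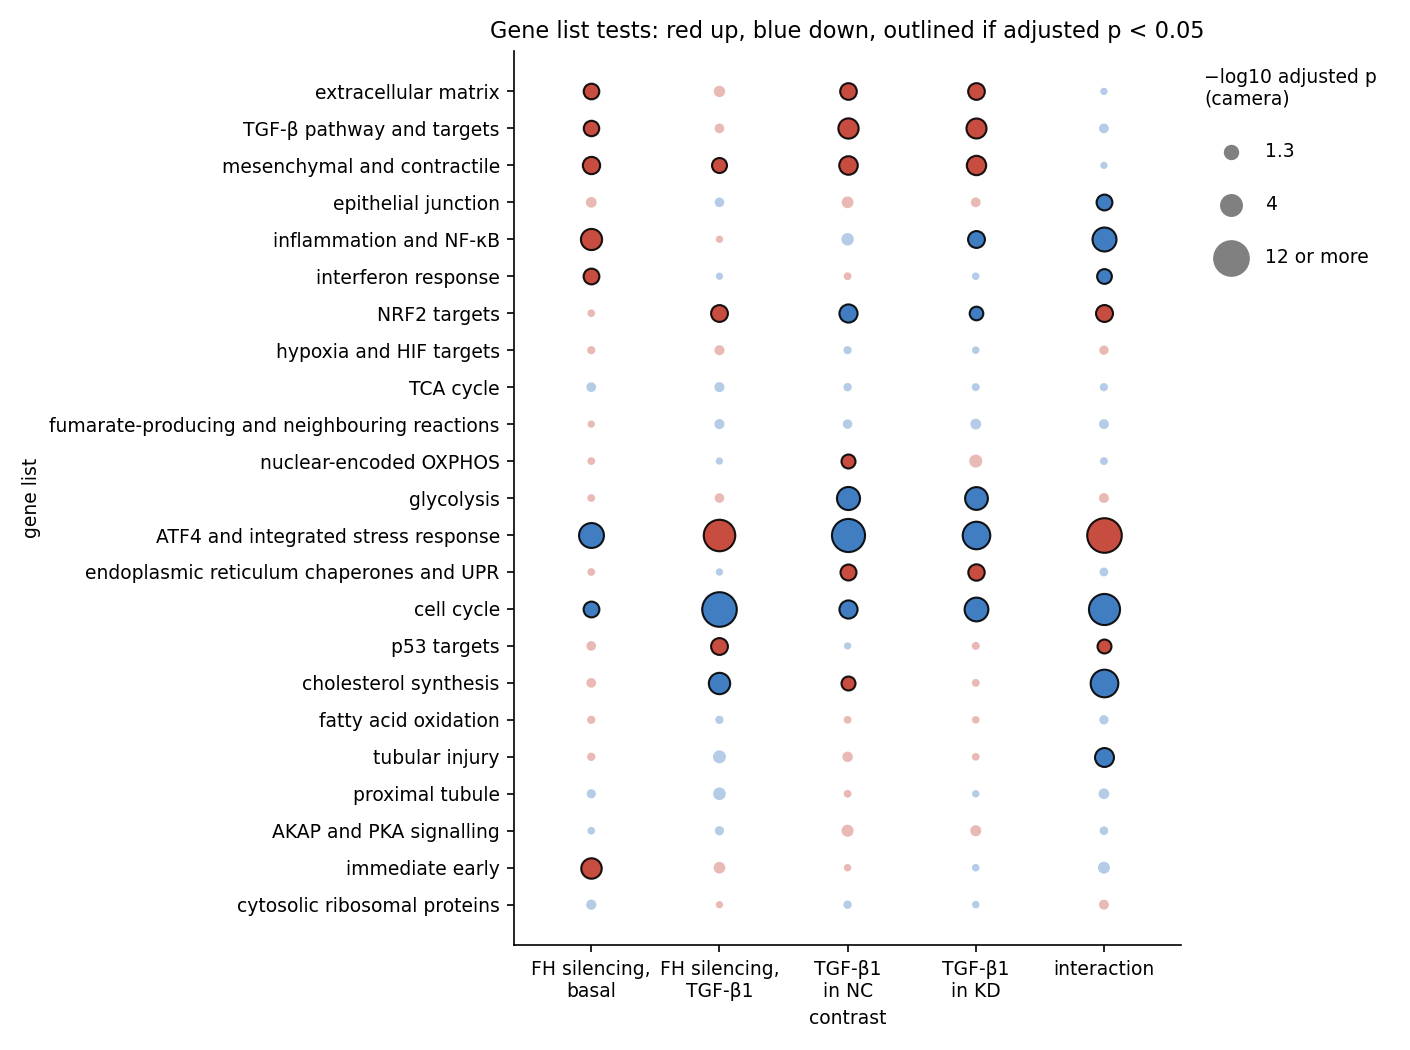
Gene lists (vertical axis) against the 5 comparisons (horizontal axis); the size of a dot gives the adjusted p of the list test, red a higher and blue a lower list, and an outline a call at 0.05. The ATF4 list is lower with silencing in basal cells (adjusted p = 1.09e-06) and higher with silencing in TGF-β1 libraries (adjusted p = 1.34e-10).

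The basal count and its balance depend on the libraries and the scaling. It was 272 without NC replicate 2 and 212, 219 and 270 without KD replicates 1, 2 and 3, and 151 with only the 2 groups compared fitted. In the basal comparison 39.4% of the called genes were higher, against 53.8% by limma on TPM, 51.0% with only the 2 groups compared fitted and 41.5 to 50.4% without 1 library. The list call of the matrix was lost without NC replicate 1 (adjusted p = 0.0905), and that of interferon also without NC replicate 1 (0.0597). The TGF-β pathway lost its call without NC replicate 3 (0.0589) or KD replicate 3 (0.07), and the cell cycle without NC replicate 3 (0.0568). Kif12, Nedd9 and Prkch each lost their call in 5 of 6 fits without 1 library (adjusted p up to 0.156, 0.148 and 0.165). C1qtnf1, Col12a1 and Dusp5 lost it in 3 (up to 0.0948, 0.0934 and 0.0827), Cxcl2 without KD replicate 2 (0.0554) and Tpx2 without NC replicate 3 (0.0617).

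The genes that fell with silencing in both settings shared short sequence words in their 3' UTRs. Of 165 such genes with an annotated 3' UTR, 60 (36.4%) held the 7-base word TCTACAC, against 15.5 expected from genes of like UTR length (adjusted p = 1.26e-13, Bonferroni over 16384 words). The words CTACACA (9.85e-08), TTCTACA (0.00317) and GACACCT (0.00466) passed the same test at 0.01. At least 1 of these 4 words was found in 113 of the 165 genes (68.5%, against 33.5% expected) and in 23.3% of the genes higher in both (28.1% expected). Among all genes lower in basal cells the share was 64.0% (34.1% expected) and with TGF-β1 45.0% (29.5% expected). Both sets include the 165 genes in which the words were picked, so these shares are no separate evidence. Rrm1, Tpx2, Sh3yl1, Prkch, Shmt2, C1qtnf1 and Nedd9 hold a word. So do some genes that rose in basal cells, F3, Txnip, Cxcl2, Klf6, Col4a1 and Ccn1 among them. Of the genes called in basal cells, 221 (129 higher, 92 lower) were left without those that hold a word or have no annotated 3' UTR. This comparison was chosen after seeing the data, and no gene was tested anew. The words were picked in genes called lower, so leaving their carriers out raises the share of higher genes by construction. With the lists tested again on the genes left, those of inflammation (adjusted p = 0.000868), ATF4 (1.83e-06) and immediate early genes (0.0416) kept their basal call. Those of the matrix (0.0683), the TGF-β pathway (0.22), mesenchymal genes (0.0566), interferon (0.0592) and the cell cycle (0.0592) lost it. Fewer members were left, such as 16 of the TGF-β pathway and 17 of interferon, and 0 called interferon genes hold a word. A lost call alone does not show that a list rests on such genes.

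**Figure D3:**
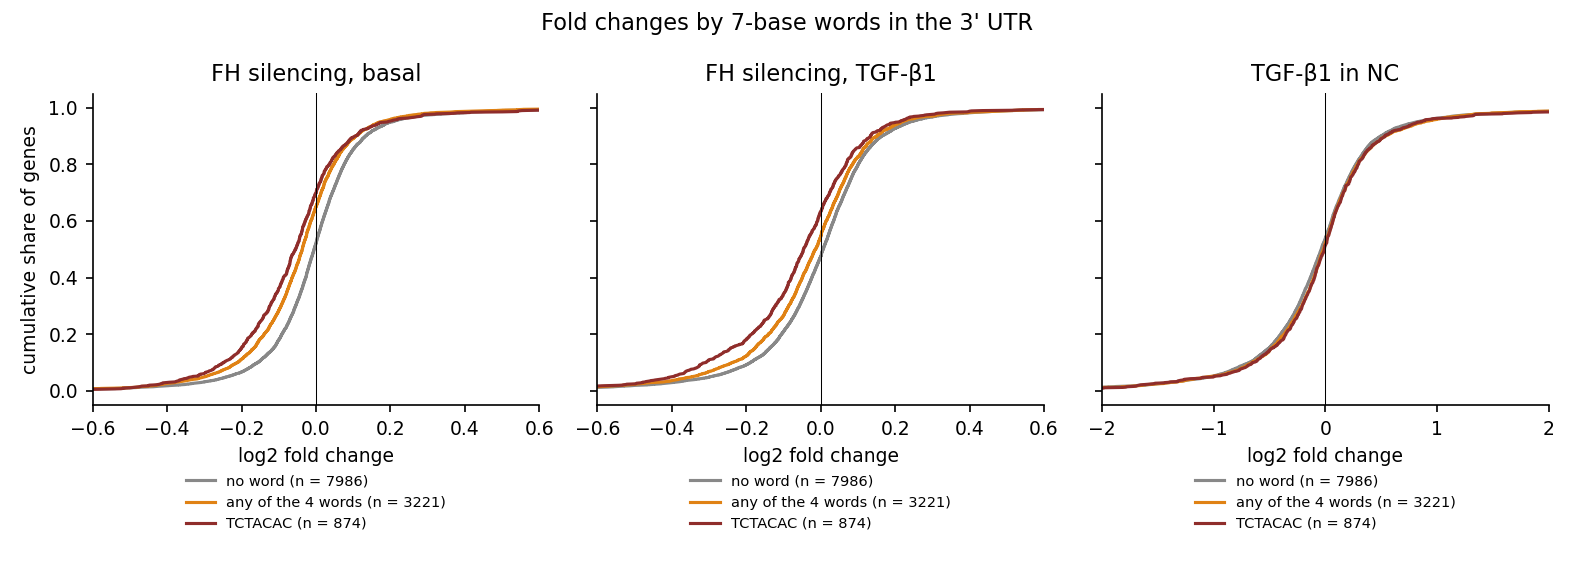
Cumulative share of genes (vertical axis) by log2 fold change (horizontal axis) with Fh1 silencing, basal and with TGF-β1, and with TGF-β1 in control cells. Curves are for genes with none of the 4 words in the 3' UTR, for the 3221 genes with any of them and for the 874 with TCTACAC. Averaged over strata of UTR length, which the curves do not show, the median of genes with TCTACAC differed from that of all genes without it. With silencing the difference was -0.035 in basal cells and -0.057 with TGF-β1, and -0.015 and -0.031 among genes called in neither.

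In cells given TGF-β1, silencing of Fh1 went with higher transcripts of the ATF4 program and lower transcripts of the cell cycle. It called 1340 genes (635 higher, 705 lower) with a median change of 1.16-fold, 16 of them past 2-fold. No overlap between the groups was seen for 32.2% of the genes tested (10% by chance) and for 1337 of those called. Acta1, skeletal muscle actin, whose reads are hard to tell from those of Acta2, rose from 42, 35 and 50 to 98, 101 and 98 counts (Entrez 11459; log2 change 1.225, SE 0.149, adjusted p = 0.000176). Mbd6 rose by 1.05 (SE 0.055, adjusted p = 6.82e-08). So did the phosphatase Ptpn22 (19260) by 0.69 (adjusted p = 3.63e-05) and the cystine transporter Slc7a11 (26570) by 0.655 (adjusted p = 0.0057). F3 rose by 0.585 (adjusted p = 6.04e-07) and the sorting nexin Snx30 (209131) by 0.58 (adjusted p = 0.000321). Besides Fh1, the potassium channel Kcnj16 (16517; -1.14, adjusted p = 1e-05) and myosin light chain kinase Mylk (107589; -0.77, adjusted p = 0.000314) fell most by the fixed rule. They were followed by Gpd1l (333433; -0.76, adjusted p = 3.96e-08), C1qtnf1 (-0.74, adjusted p = 0.00135) and the trafficking protein Vipas39 (104799; -0.71, adjusted p = 9.01e-07). Gpd1l, C1qtnf1 and Vipas39 hold one or more of the 4 words.

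Of the 33 ATF4 genes, 19 rose and 1 fell with silencing in TGF-β1 libraries (20 and 1 adjusted over the list alone; adjusted p = 1.34e-10). Slc7a11 is one of them, with the stress sensor Sesn2 at 0.43, the transcription factor Ddit3 at 0.36 and Nupr1 at 0.33. Of 28 NRF2 targets, 8 rose and 2 fell (14 and 2 adjusted over the list alone; adjusted p = 0.0037, and adjusted p = 0.0538 with an estimated correlation). The exporter Abcc4 rose by 0.46 and heme oxygenase Hmox1 by 0.43, while the glutathione transferase Gstm1 changed by -0.48. Of 23 p53 targets, 7 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.0037). Beside Sesn2 these were, among others, the antiproliferative Btg2 at 0.44, Pmaip1 at 0.30 and Gadd45a at 0.30. Of the mesenchymal and contractile genes, 4 rose (5 adjusted over the list alone; adjusted p = 0.0152, and adjusted p = 0.0538 with an estimated correlation). They were the integrins Itga5 (0.25) and Itgb1 (0.10), Cnn2 (0.18) and the tropomyosin Tpm4 (0.14). Of the 40 cell cycle genes, 23 fell and 0 rose (27 and 0 adjusted over the list alone; adjusted p = 9.18e-15). Rrm1 was at -0.46, cyclin Ccne1 at -0.36, the replication factor Cdc6 at -0.35 and Tpx2 at -0.33. Of 25 genes of cholesterol synthesis, 8 fell (13 and 1 higher adjusted over the list alone; adjusted p = 5.9e-05, and adjusted p = 0.0504 with an estimated correlation). Hmgcs1, HMG-CoA synthase, was at -0.48, Sc5d at -0.38, Acat2 at -0.26 and Pmvk at -0.21. By camera, the matrix list was not called here (8 rose and 3 fell, adjusted p = 0.155). Nor were the TGF-β pathway (6 and 4, 0.369) and inflammation (5 and 5, 0.943). Immediate early (3 and 1, 0.131) and interferon genes (1 and 0, 0.979) were not called either. By fry, the matrix (adjusted p = 0.00374) and immediate early genes (0.0034) tested as higher. Inflammation tested as lower by fry (0.00374). Of the markers named in advance, Ccn2 rose by 0.24 (adjusted p = 0.000582) and Fn1 by 0.16 (adjusted p = 0.00195). Smad7 (0.08, adjusted p = 0.256), Cdh1 (0.02, adjusted p = 0.635), Col1a1 (-0.05, adjusted p = 0.885) and Ccl2 (-0.37, adjusted p = 0.408) did not pass. Nor did Acta2 (40, 47 and 55 counts against 58, 54 and 57, adjusted p = 0.397) and Vim (6, 12 and 13 against 50, 12 and 9, adjusted p = 0.227).

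The count with TGF-β1 was 888 without NC+TGF-β1 replicate 3 and 857, 872 and 787 without KD+TGF-β1 replicates 1, 2 and 3, and it was 889 by DESeq2. Pmaip1 lost its call in each of 6 fits without 1 library (adjusted p up to 0.092), Itgb1 in 5 (up to 0.135), Gadd45a in 3 (up to 0.056) and Pmvk in 3 (up to 0.0882). Without the genes that hold a word, 852 of the calls were left (476 higher, 376 lower), a shift the choice of words brings by construction. With the lists tested again on the genes left, the mesenchymal list lost its call (adjusted p = 0.141). That of tubular injury gained one, as lower (adjusted p = 0.0432).

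KD+TGF-β1 replicate 1 held reads of pluripotency transcripts that the other libraries lack. The 9 markers Zfp42, Dppa5a, Nanog, Nr0b1, Sall4, Fgf4, Gdf3, Tcl1 and Utf1, noticed in the data, had 328 estimated counts there and 0 in the other 11 libraries. In all, 61 genes had 3 or more counts there and 0 elsewhere, against 0 to 3 such genes in each other library. None of the 9 is among the genes tested, but tested markers were also higher there than in replicates 2 and 3 of the group. Esrrb had 68 counts against 11 and 9, and Sox2 80 against 34 and 40. Sox2 was not higher there than in the basal libraries, with 104, 86 and 105 counts in NC and 84, 94 and 87 in KD. Without KD+TGF-β1 replicate 1 silencing with TGF-β1 called 857 genes. It called 872 and 787 without replicates 2 and 3, so the count of 857 is no measure of these reads.

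**Figure D4:**
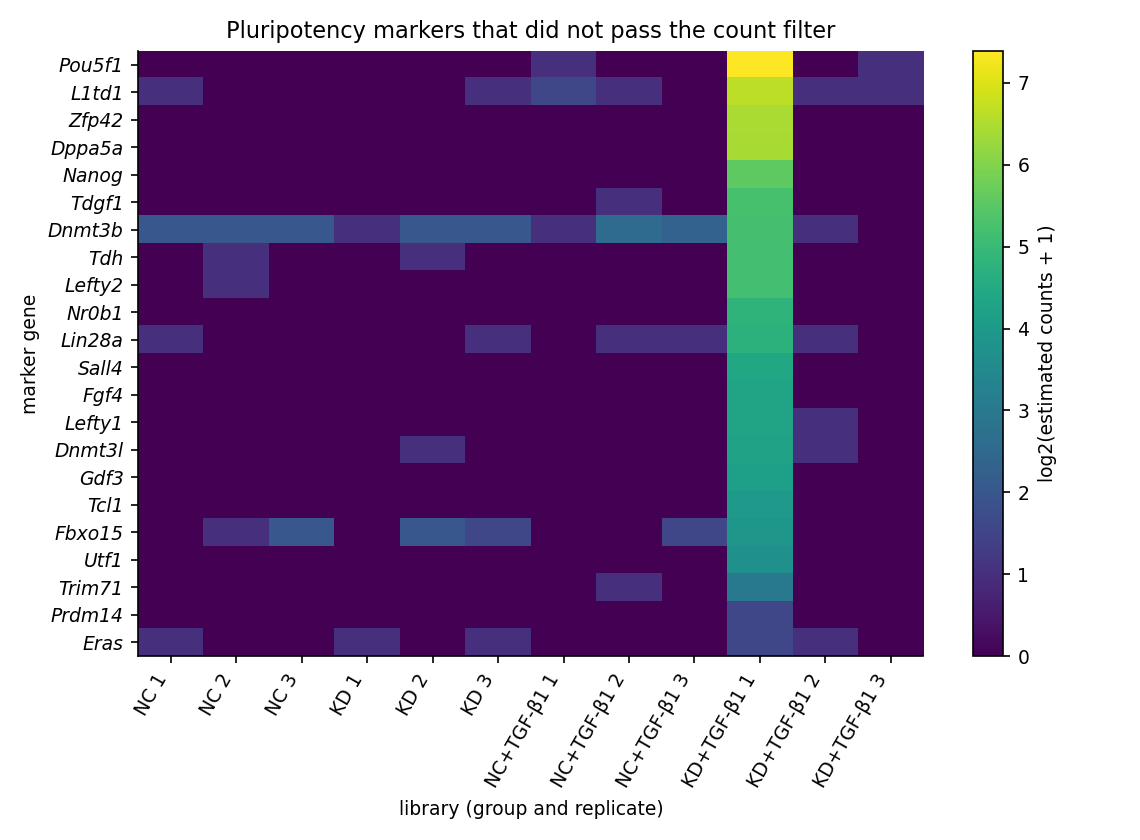
Estimated counts (color, log2 of count + 1) of pluripotency markers that did not pass the count filter, by library (horizontal axis) and gene (vertical axis). The markers that were noticed have 328 counts in KD+TGF-β1 replicate 1 and 0 in the other 11 libraries.

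In TGF-β1 libraries, transcripts of the contractile program were higher than in basal ones and those of the ATF4 program lower, in control and in silenced cells. The lists of the matrix and the TGF-β pathway tested as higher in both, and those of glycolysis, NRF2 and the cell cycle as lower. With an estimated correlation between genes the matrix, glycolysis and NRF2 lost their call in both, and the TGF-β pathway and the cell cycle in control cells. The comparison called 7511 genes in control cells (3443 higher, 4068 lower) and 7616 in silenced cells (3671 higher, 3945 lower). They had a median change of 1.31-fold in both and 1063 and 1140 genes past 2-fold. No overlap was seen for 65.9% and 72.9% of the genes tested (10% by chance) and for 7152 and 7491 of those called. In control cells Fn1 rose from 2043 ± 70.9 to 8204 ± 117 CPM (log2 change 2.01, SE 0.028, adjusted p = 1.04e-15). Ccn2 rose by 1.90 (adjusted p = 1.45e-14) and the pathway's inhibitor Smad7 by 1.40 (adjusted p = 2.85e-12). Cdh1 rose by 0.28 (adjusted p = 2.12e-07) and Col1a1 from 8, 17 and 13 to 94, 109 and 126 counts (adjusted p = 1.29e-08). Ccl2 (-0.89, adjusted p = 0.002) and Hmox1 (-0.31, adjusted p = 0.000688) fell. In silenced cells Fn1 rose by 2.07, Ccn2 by 1.94, Smad7 by 1.37, Col1a1 by 3.06 and Cdh1 by 0.21, and Ccl2 was at -1.86, with adjusted p of 8.33e-16 to 2.9e-06. Hmox1 was at 0.07 (adjusted p = 0.33). Acta2, smooth muscle actin, had 2, 1 and 0 counts in NC and 40, 47 and 55 in NC+TGF-β1 libraries. It had 1, 1 and 2 in KD and 58, 54 and 57 in KD+TGF-β1 libraries. Vim did not pass in control cells (adjusted p = 0.224). In silenced cells it went from 3, 1 and 4 to 50, 12 and 9 counts (log2 change 3.17, adjusted p = 0.00244; 2.02, still called, without KD+TGF-β1 replicate 1).

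The largest increases in control cells by the fixed rule were those of Mcam (Entrez 84004; 89.7-fold, adjusted p = 5.16e-14), a cell adhesion molecule, and Clu (12759; 61.7-fold, adjusted p = 9.14e-19), the secreted chaperone clusterin. They were followed by the actin-binding Cotl1 (72042; log2 change 5.56), Cd40 (21939; 4.81), Ccn4 (22402; 4.79) and the hyaluronan synthase Has2 (15117; 4.6). The largest decreases were those of the chemokine Ccl20 (20297; 50.6-fold), Sprr1a (20753; -4.83), and the peptidylarginine deiminase Padi1 (18599; -4.49). Next were the alarmin Il33 (77125; -4.23) and the interferon-induced Ifit3b (667370; -4.21) and Ifit3 (15959; -3.92). In silenced cells Mcam (6.45), Cotl1 (6.30), Clu (5.91), the kinase Fgr (14191; 4.88), Acta1 (4.67) and Has2 (4.44) rose most. There Ccl20 (-5.66), Il33 (-5.11), Sprr1a (-4.82), Ifit3b (-4.52), the ubiquitin ligase Pdzrn3 (55983; -4.18) and Ifit3 (-4.175) fell most. The adjusted p of these genes were 9.14e-19 to 5.8e-10. Reads of Ifit3 and Ifit3b are hard to tell apart.

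Of the 31 matrix genes, 15 rose and 6 fell in control cells, and as many in silenced cells (adjusted p = 0.00436 and 0.0042; adjusted p = 0.0993 and 0.107 with an estimated correlation). Those that rose include the gelatinase Mmp9 (log2 change 3.57 in control, 3.91 in silenced cells), Col6a1 (3.48 and 3.21) and tenascin Tnc (3.21 and 3.2). In silenced cells Fbln5 rose from 0, 2 and 1 to 16, 8 and 15 counts. Of the 31 genes of the TGF-β pathway and its targets, 21 rose and 7 fell in each (adjusted p = 0.000177 and 0.000221; in control cells adjusted p = 0.0527 with an estimated correlation). The cytokine Il11 rose by 3.29 and 3.04 and Nedd9 by 2.61 and 2.655, with the co-receptor Tgfbr3 going from 18, 8 and 17 counts to 0, 2 and 0 in control cells. Of the 19 mesenchymal and contractile genes, 13 rose and 3 fell in control cells (adjusted p = 0.000871) and 15 and 2 in silenced cells (adjusted p = 0.000404). Tagln, a smooth muscle protein, went from 2, 0 and 0 to 24, 18 and 29 counts in control and from 0, 1 and 1 to 46, 33 and 28 in silenced cells. In control cells the transcription factor Snai1 went from 2, 4 and 5 to 26, 24 and 27 and the tropomyosin Tpm2 from 1, 1 and 2 to 10, 10 and 7. Of 19 chaperones and genes of the unfolded protein response, 12 rose and 4 fell in control cells (adjusted p = 0.00743, and adjusted p = 0.0527 with an estimated correlation). In silenced cells 13 rose and 2 fell (adjusted p = 0.00532). The transcription factor Xbp1 was at 0.83 and 0.75, Manf at 0.79 and 0.62, Edem1 at 0.675 in control cells, Pdia3 at 0.615 in silenced cells and Herpud1 at -0.81 and -0.60. In control cells 20 of 45 nuclear-encoded genes of oxidative phosphorylation rose and 3 fell (19 and 3 adjusted over the list alone; adjusted p = 0.0313, and adjusted p = 0.336 with an estimated correlation). In silenced cells 22 rose and 5 fell (22 and 4 adjusted over the list alone; adjusted p = 0.057, and adjusted p = 0.0406 without KD+TGF-β1 replicate 1). The largest changes in control cells were those of Uqcrh (0.33), Cox5b (0.30), Uqcrc1 (0.29) and Ndufa4 (0.29). In control cells 15 of 25 genes of cholesterol synthesis rose and 5 fell (adjusted p = 0.0313, and adjusted p = 0.216 with an estimated correlation), while 10 rose and 8 fell in silenced cells (adjusted p = 0.784). In control cells the regulator Insig1 was at 1.03, Cyp51 at 0.73, Hsd17b7 at 0.56 and Msmo1 at 0.46.

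Of 18 genes of glycolysis, 16 fell and 2 rose in each (adjusted p = 9.22e-06 and 1.27e-05; adjusted p = 0.0993 and 0.107 with an estimated correlation). The phosphofructokinase Pfkp was at -1.29 in control and -1.02 in silenced cells and Pfkl at -1.265 and -1.37, Aldoc at -1.03 and -1.33 and lactate dehydrogenase Ldha at -0.87 and -0.89. Of the 33 ATF4 genes, 31 fell and 2 rose in control cells (adjusted p = 1.13e-11) and 28 fell and 3 rose in silenced cells (adjusted p = 3.72e-08). Nupr1 was at -2.48 and -1.89 and Vldlr at -1.79 and -1.35. Slc7a11 (-1.955) and the cystathionine lyase Cth (-1.71) are further examples from control cells. In silenced cells Gdf15 was at -1.47 and the hormone Fgf21 rose by 2.53. Of the 28 NRF2 targets, 21 fell and 3 rose in control cells (adjusted p = 0.00124, and adjusted p = 0.0527 with an estimated correlation). In silenced cells 17 fell and 5 rose (adjusted p = 0.0393, and adjusted p = 0.13 with an estimated correlation). Among them Gstm1 was at -1.75 and -2.04, Gsta3 at -1.375 in control cells, Gsta4 at -1.26 and Gstm2 at -1.08 in silenced cells. Gsta1 went from 21, 18 and 25 counts to 2, 1 and 2 in control cells; reads of these transferases are hard to tell apart. Of the 40 cell cycle genes, 25 fell and 2 rose in control cells (adjusted p = 0.00124, and adjusted p = 0.0527 with an estimated correlation). In silenced cells 31 fell and 2 rose (31 and 3 adjusted over the list alone; adjusted p = 4.18e-06). The cyclin Ccne2 was at -0.87 and -0.855, Ccne1 at -0.72 and -0.91 and the helicase subunit Mcm3 at -0.66 and -0.91. Mcm4 was at -0.585 in control cells and Gins2 at -0.84 in silenced cells. In silenced cells 19 of 32 genes of inflammation and NF-κB fell and 6 rose (adjusted p = 0.00365), and in control cells 19 fell and 7 rose (adjusted p = 0.0825). Those that fell in silenced cells include Ccl20, Il33 and the chemokines Cxcl5 (-3.76) and Cxcl1 (-3.405). Adjusted over the list alone, the counts of the lists called in the TGF-β1 comparisons were the same except where given. Without 1 library, the list call of cholesterol synthesis was lost (NC+TGF-β1 replicate 3, adjusted p = 0.0585), as were those of oxidative phosphorylation (NC replicate 1, 0.0745) and, in silenced cells, NRF2 (KD replicate 2, 0.0514). Without the genes that hold a word, the calls of cholesterol synthesis (0.138) and oxidative phosphorylation (0.0524) in control cells and of NRF2 (0.184) in silenced cells were lost.

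The effect of silencing differed between basal and TGF-β1 libraries most widely in the ATF4 program. The interaction, the change with silencing in TGF-β1 libraries minus that in basal ones, called 104 genes (55 higher, 49 lower) with a median of 1.24-fold. The 1 gene past 2-fold was 1700049E17Rik1 (Entrez 666214; log2 interaction 1.205, adjusted p = 0.0158), named after its values were seen. Of the 33 ATF4 genes, 16 had a higher interaction and 0 a lower one (25 and 0 adjusted over the list alone; adjusted p = 1.44e-25, and adjusted p = 0.000587 with an estimated correlation). Slc7a11 was at 0.92 (SE 0.166, adjusted p = 0.0187), and Nupr1 at 0.59 (SE 0.071, adjusted p = 0.0013). They were followed by Chac1 at 0.57 (SE 0.061, adjusted p = 0.000845) and the pseudokinase Trib3 at 0.49 (adjusted p = 0.00921). Egr1 was lower by the interaction (-0.84, SE 0.1, adjusted p = 0.0013): it stood at 24.4 CPM in NC and 43.4 in KD cells, and at 11.08 and 11.04 with TGF-β1. Lcn2, a secreted marker of tubular injury, stood at 249.7 CPM in NC and 241 in KD cells, and at 274 and 169.1 with TGF-β1 (interaction -0.645, SE 0.044, adjusted p = 8.18e-06). Among the other genes with the largest interaction by the fixed rule were Lims2 (225341; 0.90, adjusted p = 0.0239), a focal adhesion protein, the purine receptor P2rx4 (18438; 0.54, adjusted p = 0.0329) and the glycine transporter Slc6a9 (14664; 0.53, adjusted p = 0.00567). On the lower side were H1f2 (-0.75, adjusted p = 0.0489), Cd209c (170776; -0.69, adjusted p = 0.049) and Tanc2 (-0.67, adjusted p = 0.0354).

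By the interaction, of the 28 NRF2 targets Slc7a11 and Abcc4 (0.19) were higher (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.00339, and adjusted p = 0.0523 with an estimated correlation). Of the 23 p53 targets Sesn2 was higher (0.46; 4 adjusted over the list alone; adjusted p = 0.0322, and adjusted p = 0.0715 with an estimated correlation). Lower was 1 of 40 cell cycle genes, the helicase subunit Mcm2 (-0.24; 11 adjusted over the list alone; adjusted p = 2.55e-10, and adjusted p = 0.0034 with an estimated correlation). So was 1 of 25 genes of cholesterol synthesis, Dhcr7 (-0.31; 9 adjusted over the list alone; adjusted p = 3.32e-08). Of the 32 genes of inflammation and NF-κB, Lcn2, Cxcl1 (-0.64), the chemokine Cx3cl1 (-0.47) and Tnfaip3 (-0.24) were lower (9 adjusted over the list alone; adjusted p = 3.33e-06). Of 17 genes of tubular injury, Lcn2 and osteopontin, Spp1 (-0.27), were lower (4 adjusted over the list alone; adjusted p = 0.000602). The lists of 30 epithelial junction genes (adjusted p = 0.00821, and adjusted p = 0.348 with an estimated correlation) and 22 interferon genes (adjusted p = 0.0181, and adjusted p = 0.0557 with an estimated correlation) tested as lower with 0 called members, also 0 adjusted over the list alone. Their smallest p were those of Cldn4 (-0.13, adjusted p = 0.118) and Cxcl10 (-1.20, adjusted p = 0.354). Fn1 (0.07, adjusted p = 0.545), Ccn2 (0.03, adjusted p = 0.843), Smad7 (-0.03, adjusted p = 0.888) and Cdh1 (-0.06, adjusted p = 0.523) did not pass. Nor did Hmox1 (0.385, adjusted p = 0.0718), Ccl2 (-0.97, adjusted p = 0.219), Col1a1 (adjusted p = 0.951), Acta2 (0.982) or Vim (0.596).

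**Figure D5:**
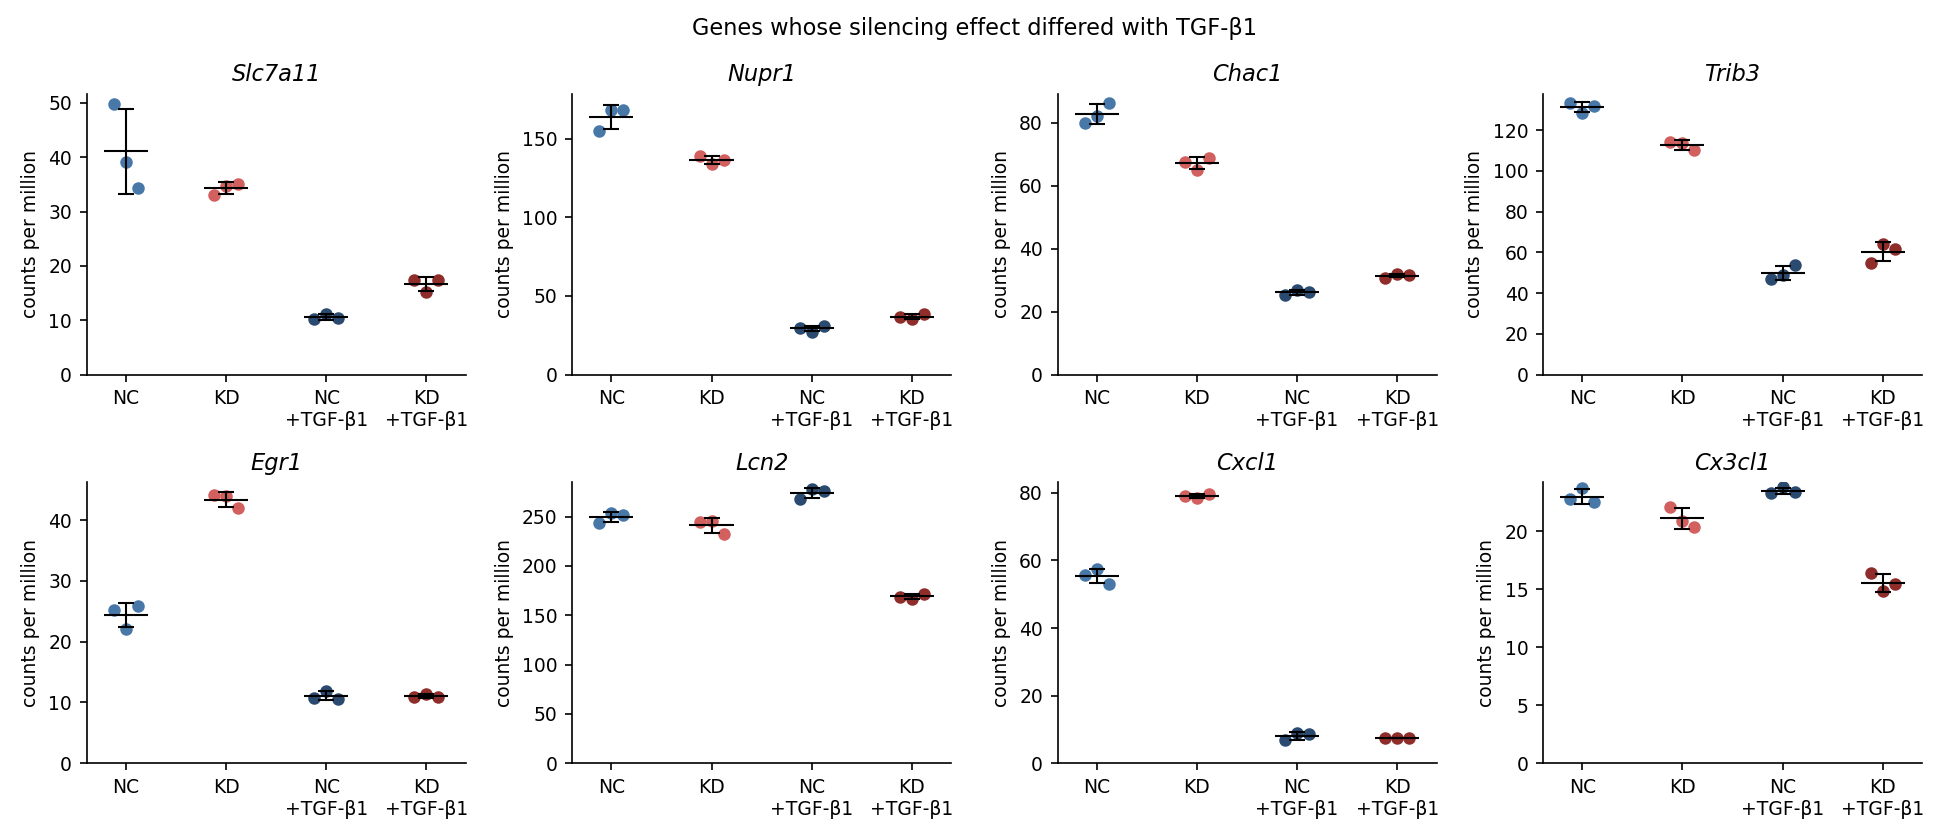
CPM (vertical axis) of 8 genes in the 4 groups, with bars for the mean of 3 libraries and error bars for ± 1 SD. With silencing, Nupr1 and Chac1 fell in basal cells and Nupr1 rose in TGF-β1 libraries (log2 interaction 0.59 and 0.57), while Egr1 rose in basal cells (interaction -0.84).

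The interaction count was 67 without NC replicate 2, and 46, 38 and 45 without KD replicates 1, 2 and 3. It was 66 and 60 without NC+TGF-β1 replicates 1 and 3, and 59, 61 and 38 without KD+TGF-β1 replicates 1, 2 and 3. With replicate number as a block it was 54. Of the genes called, 52.9% were higher, against 45.0% with size factors of DESeq2, 45.2% by limma on TPM and 41.5 to 57.9% without 1 library. The epithelial junction list lost its call without KD+TGF-β1 replicate 1 (adjusted p = 0.137), and interferon without NC replicate 1 (0.0562) or KD replicate 2 (0.0525). The p53 list lost it without NC replicate 1 (0.0987), KD replicates 1 (0.0515) or 2 (0.0633), NC+TGF-β1 replicate 3 (0.0928) or KD+TGF-β1 replicates 1 (0.0598) or 3 (0.0532). Over the 12 fits without 1 library, 9 of the 21 named genes kept their call in each. Cd209c and Tanc2 lost it in 10 (adjusted p up to 0.142 and 0.118), and Mcm2, P2rx4, Spp1 and Tnfaip3 in 9 (up to 0.144, 0.0963, 0.139 and 0.139). H1f2 lost it in 8 (up to 0.139), Lims2 and Slc7a11 in 7 (up to 0.0857 and 0.0701), Abcc4 and Dhcr7 in 5 (up to 0.0743 and 0.058) and Cxcl1 in 3 (up to 0.06). Without the genes that hold a word, 74 of the calls were left, and the epithelial junction list, tested again on the genes left, lost its call (adjusted p = 0.156).

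The comparisons that share no library were set side by side. Silencing called 104 genes higher both in basal and in TGF-β1 libraries, against 9.2 by chance, and 171 lower in both, against 15.6, with 10 called in opposite directions. Of 428 genes called in basal cells other than Fh1, 398 had the same sign with TGF-β1. Across 11706 genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.062 and a Spearman correlation of 0.314. They were 0.519 and 0.433 over the 5853 genes above the median level. For TGF-β1 in control and in silenced cells these were 0.908 and 0.919. There were 3074 genes higher in both (1079.7 by chance), 3456 lower in both (1370.6 by chance) and 9 called in opposite directions.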

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

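The 3 patterns weighed here were noticed in the data: the tests of the ATF4 list by depth of silencing and by library, both tests of the pluripotency markers, the splits for the interaction, the test of a pair of words in Fh1 and the change to a Poisson tail were chosen after the result was seen.

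The change with silencing differed between basal and TGF-β1 libraries, by the test of the interaction itself, for 9 gene lists: ATF4 (adjusted p = 1.44e-25), cell cycle (2.55e-10), cholesterol synthesis (3.32e-08), inflammation and NF-κB (3.33e-06), tubular injury (0.000602), NRF2 (0.00339), epithelial junction (0.00821), interferon (0.0181) and p53 (0.0322). With an estimated correlation between genes ATF4 (0.000587), cell cycle (0.0034), cholesterol synthesis (0.0112), inflammation (0.0034) and tubular injury (0.032) kept their call. The other 4 of the 9 lost it: NRF2 (0.0523), epithelial junction (0.348), interferon (0.0557) and p53 (0.0715). Epithelial junction also lost it without KD+TGF-β1 replicate 1 (0.137), interferon without NC replicate 1 (0.0562) or KD replicate 2 (0.0525), and p53 without NC replicate 1 (0.0987), KD replicates 1 (0.0515) or 2 (0.0633), NC+TGF-β1 replicate 3 (0.0928) or KD+TGF-β1 replicates 1 (0.0598) or 3 (0.0532). Among named genes, the same test gave a higher log2 interaction for Slc7a11 (0.92), Lims2 (0.90), Nupr1 (0.59), Chac1 (0.57), P2rx4 (0.54), Slc6a9 (0.53), Trib3 (0.49), Sesn2 (0.46) and Abcc4 (0.19). It gave a lower one for Fh1 (-0.98), Egr1 (-0.84), H1f2 (-0.75), Cd209c (-0.69), Tanc2 (-0.67), Lcn2 (-0.645), Cxcl1 (-0.64), Cx3cl1 (-0.47), Dhcr7 (-0.31), Spp1 (-0.27), Mcm2 (-0.24) and Tnfaip3 (-0.24). Of these 21 genes, 12 lost their call in 1 or more of the fits without 1 library. In each of these the cytokine and the table or experiment change together and cannot be told apart.

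The ATF4 list fell with silencing in basal cells and rose with it in TGF-β1 libraries. Deeper silencing of Fh1 in the TGF-β1 libraries, as the whole cause and acting in proportion, would put the basal median of the 33 genes at 0.085. It was -0.141, with a bootstrap SE over the 33 genes of 0.044, which does not measure the spread between libraries. The basal list test had the list as lower, where this cause puts it higher (adjusted p = 0.0182 with an estimated correlation). This argues against that cause as the whole one where it acts in proportion. A response to the depth of silencing that is not in proportion was not tested and stays open. A single outlying library is argued against too, since the largest adjusted p of the list in the interaction without 1 library was 6.88e-18. A difference between the experiments behind the tables, in cell density or medium for example, stays open beside an effect of TGF-β1 on the response to loss of Fh1.

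The genes lower with silencing in both settings are rich in 4 words of 7 bases in their 3' UTRs, the best of them with a Bonferroni p of 1.26e-13, which is consistent with pairing of the silencing RNA, through its seed, with transcripts other than Fh1. The best word, TCTACAC, is found 0 times in the coding transcript of Fh1, so an RNA that targets Fh1 through that word is argued against. Its reverse complement GTGTAGA starts at base 205 of that transcript, and GACACCT, another of the 4 words, at base 216. A pair of this kind with starts at most 16 bases apart, within a stretch of at most 23 bases, is found in 0.265% of the other tested genes (30 of 11327), so a candidate explanation is that both strands of 1 duplex against Fh1 act through their seeds. The labels do not state the reagent, and a biological cause for the words was not tested. Genes with such a word, Rrm1, Tpx2, Sh3yl1, Vipas39 and Sc5d among them, are therefore open to both readings.

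In KD+TGF-β1 replicate 1, the 9 noticed pluripotency markers, none of them among the genes tested, had 328 counts against 0 in the other 11 libraries. Tested markers were also higher there than in replicates 2 and 3 of the group. Esrrb had 68 counts against 11 and 9, and Sox2 80 against 34 and 40. Sox2 was not higher there than in the basal libraries, with 104, 86 and 105 counts in NC and 84, 94 and 87 in KD. RNA or reads of mouse pluripotent cells in that library may be the source: of 18 other markers, 13 had at most 10 counts in each of the 9 libraries of the other groups, and these 13 had 497 counts there against 2 to 9 in each of the other 11 libraries. Pou5f1 had 167 counts there and at most 1 elsewhere, and L1td1 99 and at most 2. Induction by silencing with TGF-β1 is argued against, since these 13 markers had 8 counts in replicates 2 and 3 together, under the counting limit of 16.2 set by the other 9 libraries. Where such reads came from, at culture, library or sequencing, stays open.

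Other splits of the libraries were counted for each number of called genes. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05: the real split alone (1 of 10) gave 429 genes or more for silencing in basal cells (highest other 150), 1340 with TGF-β1 (highest other 0), 7511 for TGF-β1 in control cells (0) and 7616 in silenced cells (0). For the interaction, the labels of silencing were split anew within the basal and within the TGF-β1 libraries, and 100 of 200 such splits were drawn. Of these, 8, the real one included, gave 104 genes or more (highest other 1657). In each of the 7 others the TGF-β1 libraries kept their real division, as labelled or swapped, so the change with silencing there enters the contrast. The share of 8 in 100 is therefore no measure of chance, and the splits do not exclude chance at 0.05. The 1657 genes, many times the real count, point to a structure of the samples: that split swaps the labels in the TGF-β1 libraries alone and so adds the 2 changes with silencing.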

How the results depend on the processing

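The union of both tables and leaving out genes that hold a word were chosen after the result was seen. So was the size of 0.02 below which a correlation counts as unmoved. The other alternatives were planned. No list that was called and no named gene that was called changed sign, but the balance of calls turned: in basal cells from 39.4% higher to 53.8% by limma on TPM, 51.0% with only the 2 groups compared and 50.4% without NC replicate 3. Leaving out genes that hold a word gave 58.4% there and 55.9% against 47.4% for silencing with TGF-β1, by construction, as the words were picked in genes called lower. For TGF-β1 by DESeq2 it went from 45.8% to 50.7% in control and from 48.2% to 50.9% in silenced cells. For the interaction it went from 52.9% to 45.0% with size factors of DESeq2, 45.2% by limma on TPM, and 41.5%, 46.7%, 45.9% and 42.1% without NC replicate 3, KD replicate 3 and KD+TGF-β1 replicates 2 and 3. An absolute log2 change of at least 1 left 83.3% higher in basal cells and 62.5% for silencing with TGF-β1. Of the values that answer a comparison, 253 kept their call or moved little, 43 moved and 1 gained a call; of those for named genes, 2851 kept their side of the threshold, 176 lost a call and 3 gained one; of those for lists, 466 kept it and 50 lost a call, 21 of them with an estimated correlation and 10 without genes that hold a word. With only the 2 groups compared, 151 genes were called for silencing in basal cells; by DESeq2, 889 with TGF-β1; with replicate number as a block, 54 by the interaction. An absolute log2 change of at least 1 left 6, 16, 1063, 1140 and 1 genes in the 5 contrasts, by construction. Without genes that hold a word, 221 and 852 of the main calls for silencing were left, with no gene tested anew. Without 1 library, counts ranged from 212 to 641 for silencing in basal cells, 787 to 974 with TGF-β1 and 38 to 147 for the interaction, and Fh1 with TGF-β1 in control cells from -0.115 to -0.053. Lists called for silencing went from 8 to 5 in basal cells and from 6 to 3 with TGF-β1 with an estimated correlation, to 3 in basal cells without genes that hold a word and to 13 with TGF-β1 by fry; for TGF-β1 they went to 2 (estimated correlation) and 19 (fry) in control cells and to 21 (fry) in silenced cells, and for the interaction to 5 (estimated correlation). Pearson and Spearman correlations between settings of silencing were 0.519 and 0.433 for genes above the median level and 0.012 and 0.16 with no filter; for TGF-β1 they were 0.97 and 0.951, and 0.449 and 0.621. The cause was not tested except where stated. Same-number replicates do not pair (18 correlations, -0.105 to 0.073; 2 libraries correlate best with their own number), and the block ended 1 list call, that of p53 in the interaction (adjusted p = 0.0524). At this depth genes near 0, such as Acta2 and Vim in basal cells, give no reliable fold.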

Other observations

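By camera with all libraries, lists around the silenced enzyme were not called with silencing. All changes in this and the next paragraph are those with silencing, in basal cells or in TGF-β1 libraries (with TGF-β1). The test fry asks whether the genes of a list move one way on balance and compares them with no other genes. By fry, the list of the tricarboxylic acid cycle was called as lower in basal cells (adjusted p = 0.0403) and with TGF-β1 (adjusted p = 0.0122). Targets of hypoxia and HIF were called by fry as higher with TGF-β1 (adjusted p = 0.0364). The members named here are the called ones with the largest log2 changes, and they were not followed through the alternatives. The list tests without genes that hold a word were chosen after the result was seen. Of 26 genes of AKAP and PKA signalling, Akap12 rose and Prkar2a, a regulatory subunit of protein kinase A, fell both in basal (log2 change -0.43) and in TGF-β1 libraries (-0.40), with adjusted p = 0.834 and 0.446 for the list. Prkar2a holds enriched words in its 3' UTR. Of 24 genes listed for the tricarboxylic acid cycle besides Fh1, 0 were called in basal cells (adjusted p = 0.359). The list also holds pyruvate dehydrogenase, which feeds the cycle, and cytosolic enzymes. With TGF-β1, Pdhb of pyruvate dehydrogenase rose (0.17). Dlst (-0.21) and the cytosolic Idh1 (-0.175) and Mdh1 (-0.125) fell (adjusted p = 0.303 for the list). Of 11 genes of reactions that make or use fumarate, 0 were called in basal cells and 1 fell with TGF-β1 (adjusted p = 0.982 and 0.303). Of 45 nuclear-encoded genes of oxidative phosphorylation, 1 fell in basal cells and 2 with TGF-β1 (adjusted p = 0.815 and 0.979). Of 24 targets of hypoxia and HIF, 0 were called in basal cells (adjusted p = 0.699). With TGF-β1, the glucose transporter Slc2a1 (0.235) and the growth factor Vegfa (0.19) rose and the kinase Pdk1 (-0.40) and the prolyl hydroxylase P4ha1 (-0.20) fell (adjusted p = 0.303). Of 18 genes of glycolysis, 1 fell in basal cells, and with TGF-β1 5 rose and 3 fell (adjusted p = 0.834 and 0.378).

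By camera with all libraries, lists of cell identity were not called with silencing either. By fry, tubular injury (adjusted p = 5.89e-05) and proximal tubule (adjusted p = 0.00194) were called as lower with TGF-β1. By camera, tubular injury was called as lower there without NC+TGF-β1 replicate 1 (adjusted p = 0.0267), without KD+TGF-β1 replicate 3 (adjusted p = 0.0328) or without genes that hold a word (adjusted p = 0.0432), and proximal tubule without KD+TGF-β1 replicate 2 (adjusted p = 0.0199). Of 30 epithelial junction genes, the keratins Krt8 (0.17) and Krt19 (0.12) rose in basal cells, and the tight junction genes Tjp1 (-0.26) and Cldn1 (-0.22) fell (adjusted p = 0.213). With TGF-β1, 2 rose and 5 fell, with Cldn1 at -0.44 and Tjp1 at -0.36 (adjusted p = 0.378). Tjp1 and Cldn1 both hold enriched words. Of 10 proximal tubule genes, the kidney transcription factor Pax2 fell in basal cells (-0.32) and with TGF-β1 (-0.39), there with Pax8 (-0.19), at adjusted p = 0.457 and 0.0736 for the list. Of 17 genes of tubular injury, 1 fell in basal cells, and with TGF-β1 2 rose and 5 fell, with Lcn2 at -0.70, complement C3 at -0.34, Spp1 at -0.28 and ceruloplasmin Cp at -0.25 (adjusted p = 0.641 and 0.0594). Of 19 genes of fatty acid oxidation 1 fell in each setting, of 49 cytosolic ribosomal proteins 0 changed in basal cells and 1 fell with TGF-β1, and of 19 chaperones and genes of the unfolded protein response 1 rose and 1 fell in basal cells and 1 fell with TGF-β1 (adjusted p from 0.279 to 0.979). Without NC replicate 1 the ribosomal proteins were called as lower in basal cells (adjusted p = 0.00107). Markers of other cell types had too few tested genes for a list test: 2 of podocytes, 4 of leukocytes, 1 of fibroblasts, 1 of the distal nephron and 3 of endothelium. Of these, the podocyte genes Synpo (-0.61) and Podxl (-0.22) and the leukocyte genes Cd14 (-0.26) and Csf1r (-0.19) fell with silencing in TGF-β1 libraries. The fibroblast gene Ly6a rose with silencing in basal cells (0.22).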
